A study of Mus musculus with 10 samples.

How the data were processed

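The series holds 10 RNA-seq samples of mouse bone marrow-derived macrophages, 5 untreated and 5 treated with PLG for 24 h. Per the labels' protocols, marrow cells were differentiated for 7 days with GM-CSF at 50 ng/mL, RNA was isolated with a column kit, and libraries were made with a total RNA-seq kit of NuGen. The groups and the replicate numbers 1 to 5 were taken from the sample labels. No label ties a replicate to a mouse, a culture or a sequencing batch.

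The deposited table gives FPKM, made by the authors, for 16936 protein-coding genes with 3 decimals, together with each gene's length and position per the file headers. The submitters' processing notes name cutadapt 2.10, FastQC 0.11.9, STAR 2.7.3a, featureCounts 2.0.0 and DESeq2 1.24.0 and the build GRCm38.p6, with no role or order. The annotation release, the strand setting of the counting and the handling of reads that match several genes are not given in the sources used here, so reads of overlapping genes, antisense genes and close paralogs may be divided between them. Of the gene identifiers 16485 occur in GENCODE release M21, all with the same coordinates, and 16921 match without their version. The table lists 26 symbols turned into dates and 10 symbols shared by 2 or more identifiers, and 9 genes at 0 in all samples. Histone genes carry newer symbols and were matched through their identifiers. Coordinates are those of the table, on GRCm38.

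The FPKM of low genes in a sample, multiplied by gene length, fall on whole multiples of 1 step, which gave the authors' denominator and the reads behind each value. With a tolerance of 0.1 read, at least 99.95% of the values tested were whole in each sample. The denominators were 32423304 to 72002612 reads, and the genes in the table took 28576766 to 64214554 of these, or 88.1% to 90.8%. Reads on these genes averaged 44669199 ± 14830612 (SD, 5 samples) in untreated and 43672472 ± 12182995 in PLG samples, with ranges that overlapped. At these depths 1 read on a gene of 1 kb corresponds to 0.0139 to 0.0308 FPKM. Denominators can include genes that were not used here.

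Values were analysed as log2(FPKM + 1). A gene was tested if it reached 1 FPKM in at least 5 of the 10 samples, which kept 9997 genes. Groups were compared in limma 3.58.1 (R 4.3.3) with treatment as the only term, moderated with an intensity trend and without robust fitting, and p-values were adjusted by Benjamini and Hochberg with a threshold of 0.05. Because the unit was FPKM, no count model was used for the main result. For the focus genes a two-sided exact permutation test of the mean over all assignments of 5 and 5 samples was added, and genes under the filter were taken from a fit without it.

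Before the data were examined, 37 gene lists and 24 focus genes were fixed, covering toll-like receptor and NF-kB responses, activation state, interferon, antigen presentation, lipids, stress, metabolism, cell cycle, RNA composition, the plasminogen system, phagocytosis and cell types. The 34 lists with at least 5 tested genes entered camera at a correlation of 0.01, which compares a list with the other genes, with Benjamini-Hochberg adjustment over the lists. Camera with an estimated correlation and fry, which asks whether a list's genes move on balance one way without comparing them with other genes, were alternatives. List members absent from the table were not analysed here. Named genes were chosen by a rule fixed at the same time: the 12 largest changes in each direction among genes past the threshold with a mean of at least 2 FPKM, groups that did not overlap and a symbol that is not a gene model, the focus genes, up to 4 members per list with the smallest p, and up to 2 of the most abundant members per list that did not pass. Some genes that the rule names were not used here.

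The model was tested on simulated data for this comparison, with 9997 genes drawn from the measured means and spreads. It recovered 36% of 50 genes changed by a fold of 1.25, 74% at 1.5, 92% at 2 and 98% at 4, and called 5 of 9797 unchanged genes. Of 20 random lists 0 were called, and a list of changed genes passed. The genes were drawn independently of each other, while the estimated correlation within the real lists reached 0.52. The simulated lists therefore do not test camera's preset correlation. The simulation also changed a far smaller part of the genes than was called in the data.

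Alternatives fixed at the same time as the lists were pseudocounts of 0.1 and 5, no filter and a filter of 5 FPKM, scaling to a common sum, median-of-ratios scaling, quantile normalization, removal of mitochondrial genes, eBayes without trend or with robust fitting, array quality weights, a replicate block, a fold of at least 2 and leaving out each sample. Added after seeing the data were voom on the recovered reads, removal of 3 repeat-like gene models, their level as a covariate, leaving out the 3 samples lowest in them, and removal of trends with GC content or gene length. Removal of the mitochondrial genes or of the repeat-like models was followed by scaling to a common sum. The effects of these removals include that of the scaling. GC content came from the transcripts of GENCODE M21 for 99.98% of the tested genes. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 was used for the recovery of reads, tests of gene families and figures. Permutation tests were run in R.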

Results

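RNA was sequenced from cultured mouse bone marrow-derived macrophages, cells grown out of bone marrow for 7 days in GM-CSF at 50 ng/mL. GM-CSF is a cytokine that turns marrow precursors into cells with macrophage and dendritic cell features. The 10 samples formed 2 groups: 5 samples were left untreated and 5 were exposed to PLG, human plasminogen per the series' design text, for 24 h. Plasminogen is the circulating precursor of the protease plasmin. The series' title is about activation of macrophages by plasminogen through the receptor Tlr2. The comparison of the groups addresses the response to PLG, and since no sample lacks or blocks Tlr2, it does not test the receptor's part. No label names a control preparation, so effects of plasminogen itself cannot be told apart from those of anything else in the added material. Expression was given as FPKM for 16936 protein-coding genes. The reads behind these values, recovered from the steps of the low values, came to 28576766 to 64214554 per sample. Nothing in the labels says whether the replicates came from separate mice or cultures, so the p-values measure the spread between these samples only, which may be technical. Values below are means ± SD over 5 samples per group, and fold changes are on the log2(FPKM + 1) scale, which understates the change of genes with low values.

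Expression differed between PLG and untreated samples for 6040 of the 9997 genes tested, 60.4% of them. With limma and Benjamini-Hochberg adjustment, 2914 genes were higher and 3126 lower with PLG than in untreated samples. On the log2(FPKM + 1) scale the changes upward were the larger ones. By a fold of 2 or more 835 genes rose and 567 fell, and by a fold of 16 or more 36 rose and 0 fell. The added 1 limits the fall of genes with low values. Plain ratios of FPKM, such as those of Ccr2 and Gas6 below, can therefore exceed 16. All 5 samples of a group lay beyond all 5 of the other for 47.2% of the tested genes, where chance gives 0.794%. Samples correlated at 0.976 to 0.995 within a group and at 0.847 to 0.868 between groups, and the first principal component, with 85.7% of the variance, separated the groups.

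The genes with the steepest rise included those of secreted mediators of inflammation and of enzymes that make them. Il1b (ENSMUSG00000027398.13, chromosome 2, 129364570 to 129371139), the gene of the cytokine interleukin 1 beta, went from 1.33 ± 0.438 to 1323 ± 85.9 FPKM, a log2 fold change of 9.17 (SE 0.106, limma adjusted p = 1.56e-15). The chemokine gene Ccl5 went from 12.3 ± 4.24 to 2249 ± 133 FPKM, and Ptgs2, the inducible cyclooxygenase of prostaglandin synthesis, from 0.629 ± 0.258 to 219 ± 6.49 FPKM. Among the 12 genes with the largest rise were also Il1a (6.81 ± 0.604 to 727 ± 46.2 FPKM) and Lcn2, whose product binds iron-carrying siderophores (0.597 ± 0.224 to 182 ± 13.1 FPKM). The same 12 held Oasl1 (0.615 ± 0.329 to 95.7 ± 5.38 FPKM), Susd2 (0.11 ± 0.0828 to 63.9 ± 5.02 FPKM) and Nos2, the inducible nitric oxide synthase (0.553 ± 0.281 to 78.8 ± 5.58 FPKM). The 12 with the largest fall were led by Ccn3 (93.9 ± 21.1 to 5.38 ± 1.40 FPKM, log2 fold change -3.89, SE 0.176, limma adjusted p = 2.84e-10). They also held Klk1b11 (116 ± 13.6 to 7.32 ± 1.93 FPKM), Asgr2 (23.9 ± 5.35 to 0.952 ± 0.326 FPKM) and Mrc1, the mannose receptor (58.8 ± 3.81 to 3.76 ± 0.490 FPKM). Mamdc2, Cd93, Ccr2, Gas6, Tifab, Tns1, Naaa and Pld4 made up the rest, with log2 fold changes between -3.35 for Mamdc2 and -2.89 for Pld4. Reads of Klk1b11 may be shared with the other genes of the kallikrein 1 family, so its level is uncertain.

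**Figure D1:**
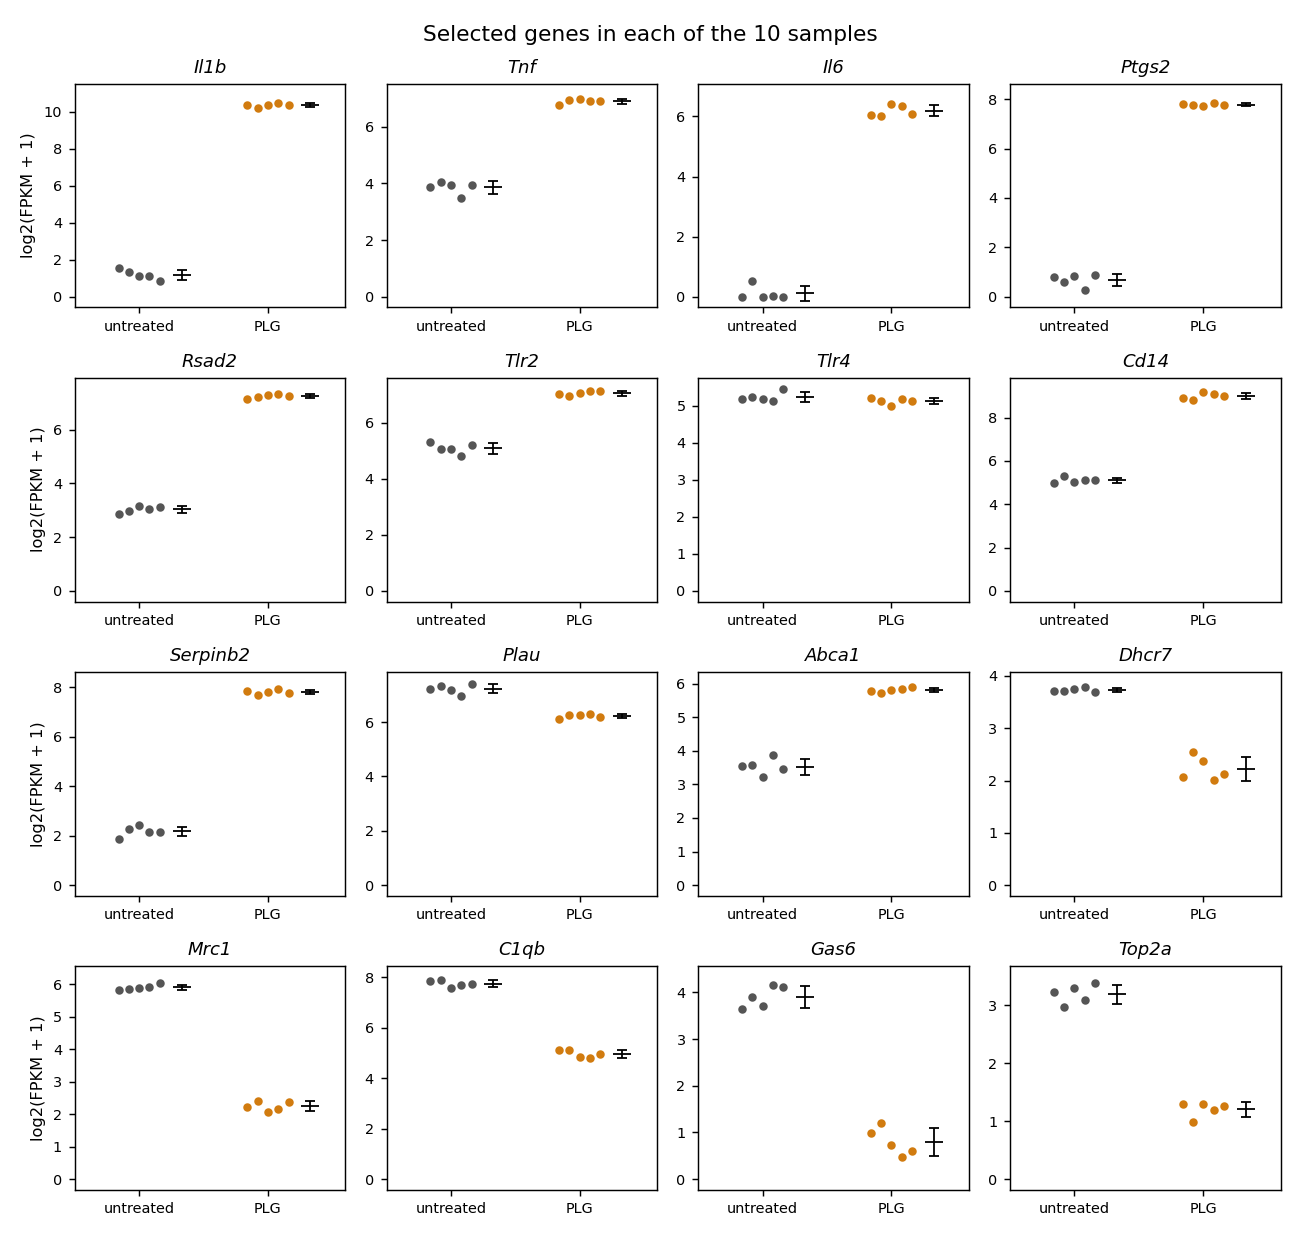
Expression of 16 genes as log2(FPKM + 1) in each sample: grey points are the 5 untreated samples, orange points the 5 PLG samples, and the bar beside them is the mean with its SD. All 5 PLG points lie above or below all 5 untreated points in every panel except Tlr4, where the groups overlap.

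Cytokine genes rose almost throughout the list fixed for them. Of 18 tested inflammatory cytokine genes, 17 rose and 0 fell, with a median log2 fold change of 2.45 (camera adjusted p = 9.61e-12), and the call held with an estimated correlation. Tnf went from 13.6 ± 2.0 to 118 ± 6.85 FPKM and Inhba, a subunit of activins, from 10.8 ± 1.84 to 389 ± 16.7 FPKM. Il12a and Il12b, which encode the subunits of interleukin 12, went from 0.0234 ± 0.0307 to 25 ± 2.20 FPKM and from 1.14 ± 1.04 to 191 ± 22.8 FPKM. Untreated 3, at 2.98 FPKM, lifted the untreated mean of Il12b, with the others at 0.470 to 0.800 FPKM. Il6 was at 0 to 0.457 FPKM in the untreated samples and at 72.5 ± 9.89 FPKM with PLG, and the untreated mean rests on untreated 2, since the other untreated samples were at 0.013 FPKM or below (log2 fold change 6.08, SE 0.119, limma adjusted p = 9.52e-14). Il18 was at 1.48 ± 0.808 FPKM in untreated samples and 1.10 ± 0.679 FPKM with PLG and did not pass the test. Il10, which encodes an anti-inflammatory cytokine, lay under the expression filter, with 0 reads over the 5 untreated libraries and 112 over the 5 PLG libraries. That is at least 38.8-fold higher against a floor of 3 reads over the untreated group, and every PLG library held reads (limma adjusted p = 0.0242 in the fit without the filter). Such bounds cover counting error only.

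Chemokine genes moved largely upward, 12 of 15 tested rising and 1 falling over all genes tested, and 2 falling when adjusted over the list alone (camera adjusted p = 2.18e-06, and adjusted p = 0.10 with an estimated correlation). The neutrophil attractants Cxcl2 (0.742 ± 0.520 to 221 ± 20.2 FPKM), Cxcl3 (1.6 ± 0.310 to 317 ± 33.2 FPKM), Cxcl1 (0.0802 ± 0.116 to 44.0 ± 7.70 FPKM) and Cxcl5 (0.428 ± 0.274 to 48.2 ± 2.62 FPKM) rose. Cxcl10 rose from 0.357 ± 0.231 to 19.8 ± 1.78 FPKM. Ccl9 and Ccl2, abundant in both groups, did not pass: Ccl9 was at 204 ± 14.3 FPKM in untreated samples and 186 ± 9.88 FPKM with PLG, and Ccl2 at 51.4 ± 6.78 FPKM in untreated samples and 58.3 ± 6.37 FPKM with PLG. In 28 alternatives Ccl9 passed as lower in 11 (adjusted p 7.76e-06 to 0.609), among them without untreated 3 (0.0256), PLG 1 (0.0481) or PLG 3 (0.0330). Ccl2 passed as higher in 4 (0.0199 to 0.904), among them without untreated 5 (0.0272).

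All 29 tested NF-kB targets and feedback regulators rose, with a median log2 fold change of 1.88 (camera adjusted p = 2.84e-17, and adjusted p = 0.0577 with an estimated correlation). NF-kB is the transcription factor family downstream of toll-like receptors. The mitochondrial superoxide dismutase Sod2 went from 11 ± 0.775 to 78.9 ± 2.41 FPKM, the NF-kB inhibitor Tnfaip3 from 6.96 ± 0.984 to 49.6 ± 1.52 FPKM, the NF-kB subunit Rel from 15.3 ± 1.27 to 65.8 ± 3.31 FPKM and the phosphatase Dusp1 from 8.26 ± 0.355 to 32.2 ± 0.575 FPKM. All 28 tested inflammatory macrophage effector genes rose as well, by a median of 3.42 (camera adjusted p = 1.99e-20, held with an estimated correlation). The glycolipid receptor Clec4e went from 10.5 ± 1.26 to 548 ± 29.8 FPKM. Of 17 tested immediate early genes, 9 rose and 5 fell, and the list did not pass (camera adjusted p = 0.0623, past the threshold in 2 of 29 camera alternatives with 0.0463 to 0.232). Rising members included Junb (35.4 ± 2.95 to 106 ± 6.88 FPKM), Nr4a2 (0.543 ± 0.394 to 12.1 ± 0.609 FPKM) and Nr4a3 (23.5 ± 4.26 to 98.5 ± 6.20 FPKM).

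Genes of the toll-like receptor pathway itself moved both ways. Tlr2 (ENSMUSG00000027995.10, chromosome 3, 83836272 to 83841767), the receptor named in the series' title, went from 33.2 ± 4.53 to 131 ± 7.07 FPKM, a log2 fold change of 1.95 (SE 0.082, limma adjusted p = 1.33e-10). Cd14, a coreceptor, went from 33.7 ± 2.92 to 508 ± 48.1 FPKM and Tlr1, a dimer partner of Tlr2, from 6.50 ± 0.660 to 17.8 ± 2.0 FPKM. The endosomal receptors Tlr8 and Tlr13 fell, from 24.1 ± 2.51 to 4.21 ± 0.645 FPKM and from 84.4 ± 2.11 to 40.3 ± 2.7 FPKM. The other partner Tlr6, at 6.91 ± 0.870 FPKM in untreated samples and 6.76 ± 0.593 FPKM with PLG, did not pass. The adaptor Myd88, at 22.8 ± 1.5 FPKM in untreated samples and 23.7 ± 1.30 FPKM with PLG, did not pass. Neither did Tlr4, at 36.7 ± 3.58 FPKM in untreated samples and 33.9 ± 1.94 FPKM with PLG. Tlr4 passed as lower in 2 of 28 alternatives (adjusted p 0.00706 to 0.694 over the 28). These were quantile normalization (log2 fold change -0.24) and removal of the repeat-like gene models with scaling to a common sum (-0.18). Of 25 tested pathway components 10 rose and 9 fell, 11 when adjusted over the list alone, and the list did not pass (camera adjusted p = 0.962). Its median of -0.11 and its mean of 0.14 differ in sign, and the test pointed upward. Of 16 inflammasome and pyroptosis genes 7 rose and 7 fell (camera adjusted p = 0.871, with a median of -0.06 and a mean of 0.16, the test pointing upward). The sensor genes Nlrp3 (15.2 ± 1.78 to 49.9 ± 1.65 FPKM) and Mefv (1.07 ± 0.276 to 9.54 ± 0.705 FPKM) and Casp4 (3.62 ± 0.800 to 15.4 ± 0.888 FPKM) rose. Txnip (39.7 ± 2.73 to 18.3 ± 1.16 FPKM) fell.

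Interferon-stimulated genes rose as a group. All 34 tested type I interferon-stimulated genes were higher with PLG, by a median of 2.36 (camera adjusted p = 1.58e-21, held with an estimated correlation). The antiviral genes Rsad2, Ifit1 and Ifit3 went from 7.19 ± 0.716 to 151 ± 7.00 FPKM, from 3.84 ± 0.857 to 143 ± 5.43 FPKM and from 2.84 ± 0.395 to 85.7 ± 8.45 FPKM. Of 16 interferon-gamma-type GTPases and their companions 15 rose and 1 fell (camera adjusted p = 7.01e-09, and adjusted p = 0.0521 with an estimated correlation). Those that rose included the guanylate-binding proteins Gbp2 (45.4 ± 4.70 to 305 ± 13.2 FPKM), Gbp3 (12.9 ± 0.782 to 90.6 ± 7.05 FPKM) and Gbp5 (2.27 ± 0.432 to 35.4 ± 1.21 FPKM) and the transcription factor Irf8 (28.1 ± 2.41 to 124 ± 6.15 FPKM). Ifnb1, the interferon beta gene, lay under the filter, with 0 reads over the untreated libraries and 13 over the PLG libraries, of which 3 held none (exact two-sided permutation p = 0.444). Gbp and Ifit genes have close paralogs, and reads may be divided among them.

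Antigen presentation genes divided by class. Of 17 tested MHC class I presentation genes 16 rose and 0 fell (camera adjusted p = 9.96e-10, held with an estimated correlation). Tapbp, which loads peptide onto class I molecules, went from 112 ± 2.64 to 284 ± 15.1 FPKM and H2-Q4 from 16 ± 1.51 to 97.0 ± 3.37 FPKM. H2-Q6 (4.73 ± 1.0 to 119.9 ± 6.55 FPKM) and H2-Q7 (1.19 ± 0.462 to 44.0 ± 2.96 FPKM) rose too, although reads cannot be assigned to these near-identical genes with certainty. Of 11 MHC class II presentation genes 1 rose and 7 fell (camera adjusted p = 0.0220, and adjusted p = 0.378 with an estimated correlation). The peptide exchange factor genes H2-DMa (42.7 ± 3.33 to 10.2 ± 0.641 FPKM) and H2-DMb1 (60.4 ± 6.15 to 28.0 ± 1.69 FPKM) fell. So did the protease gene Ctss (2688 ± 114 to 1490.2 ± 34.9 FPKM) and Ciita, the class II transactivator (14.8 ± 2.27 to 8.61 ± 0.730 FPKM). The class II beta chain H2-Eb1 was at 234 ± 18.8 FPKM in untreated samples and 244 ± 35.8 FPKM with PLG and did not pass.

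Genes of alternative activation and of clearance of dying cells fell in larger part with PLG. Of 17 tested alternative activation genes 11 fell and 4 rose, 5 when adjusted over the list alone (camera adjusted p = 0.0351, and adjusted p = 0.378 with an estimated correlation). Beside Mrc1, the list's falling members included Klf4 (29.2 ± 3.45 to 5.76 ± 1.2 FPKM) and Ptgs1 (32.2 ± 2.79 to 12.4 ± 0.950 FPKM). Tgm2 rose (8.50 ± 0.897 to 38.2 ± 2.74 FPKM). With a filter of 5 FPKM its median was -0.32, against -1.31, and it did not pass (camera adjusted p = 0.349, and 0.00468 to 0.378 over its 29 camera alternatives). Chil3 was at 118 ± 11.9 FPKM in untreated samples and 116 ± 8.06 FPKM with PLG, Pdcd1lg2 at 22.2 ± 3.64 FPKM in untreated samples and 26.3 ± 2.90 FPKM with PLG, and these did not pass. Chil3 passed as lower in 1 of 28 alternatives (adjusted p 0.00486 to 0.948) and Pdcd1lg2 as higher in 5 (0.0107 to 0.235), among them without untreated 5 (0.0411). Arg1 lay under the filter, at 0.376 ± 0.236 FPKM in untreated samples and 0.565 ± 0.196 FPKM with PLG. Of 20 efferocytosis and bridging molecules 15 fell and 4 rose, with a median of -1.65 (camera adjusted p = 5.43e-05, and adjusted p = 0.0521 with an estimated correlation). The complement chains C1qb (214 ± 18.9 to 30.2 ± 3.15 FPKM) and C1qc (68.1 ± 5.06 to 11.4 ± 0.984 FPKM) fell, as did Gas6, which bridges dying cells to receptors (14.1 ± 2.44 to 0.767 ± 0.370 FPKM), Mfge8 (513 ± 10.4 to 228 ± 11.3 FPKM) and Anxa1 (617 ± 29.4 to 194 ± 11.6 FPKM). The Gas6 receptor Axl was at 119 ± 5.81 FPKM in untreated samples and 126 ± 7.47 FPKM with PLG and did not pass, although with quantile normalization it passed as lower (log2 fold change -0.16) and with voom on the recovered reads as higher (0.13; adjusted p 0.0277 to 0.848 over 28 alternatives). Of 14 Fc and complement receptors and related genes 4 rose and 7 fell (camera adjusted p = 0.313). C3ar1 (85.6 ± 5.85 to 22.9 ± 1.71 FPKM) and Itgax (270.2 ± 14.9 to 156 ± 6.59 FPKM) fell. Cfb (0.265 ± 0.294 to 13.1 ± 2.14 FPKM) and C3 (109 ± 3.67 to 221 ± 13.3 FPKM) rose.

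The plasminogen system showed its own genes moving apart. The plasminogen activator Plau and its receptor Plaur fell, from 149.6 ± 17.1 to 73.9 ± 3.38 FPKM and from 141 ± 11.2 to 92.8 ± 4.75 FPKM. The activator inhibitor Serpinb2 rose from 3.53 ± 0.593 to 222 ± 13 FPKM. Itga5 (35.6 ± 2.46 to 83.4 ± 4.38 FPKM) and the coagulation factor gene F10 (86.1 ± 6.60 to 176 ± 8.30 FPKM) rose. The plasminogen receptor genes Plgrkt (17.5 ± 1.98 FPKM in untreated samples and 15.2 ± 1.86 FPKM with PLG), Anxa2 (78.2 ± 3.53 FPKM in untreated samples and 83.8 ± 7.59 FPKM with PLG) and S100a10 (76.4 ± 6.37 FPKM in untreated samples and 67.5 ± 8.53 FPKM with PLG) did not pass. In 28 alternatives S100a10 passed as lower in 9 (adjusted p 3.68e-04 to 0.450), among them without untreated 2 (0.0435), PLG 3 (0.0398) or PLG 4 (0.0218), and Plgrkt in 5 (0.0141 to 0.343), among them without untreated 2 (0.0478) or PLG 4 (0.0331). Anxa2 passed as higher in 4 (0.0186 to 0.634), among them without PLG 2 (0.0407). Of 17 tested members 7 rose and 7 fell (camera adjusted p = 0.865), with a median of -0.18, a mean of 0.35 and a test that pointed upward. The gene Plg itself was not analysed here. Of 19 matrix proteases, inhibitors and matrix genes 10 rose and 8 fell (camera adjusted p = 0.564). Thbs1 (69.5 ± 6.74 to 484 ± 27.7 FPKM) and Mmp25 (5.28 ± 1.22 to 69.0 ± 3.0 FPKM) rose. Mmp19 (143 ± 2.91 to 42.8 ± 1.59 FPKM) and Mmp8 (387 ± 7.79 to 129 ± 8.23 FPKM) fell.

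Lipid genes fell in larger part. Of 25 cholesterol synthesis and uptake genes 17 fell, 18 when adjusted over the list alone, and 3 rose (camera adjusted p = 5.65e-04, and adjusted p = 0.128 with an estimated correlation). The synthesis genes Dhcr7 and Msmo1 went from 12.3 ± 0.387 to 3.72 ± 0.769 FPKM and from 25.8 ± 1.62 to 14.6 ± 0.436 FPKM. Pmvk rose from 14.1 ± 1.12 to 35.5 ± 2.63 FPKM. Of 25 lipid uptake, storage and PPAR target genes 18 fell and 6 rose (camera adjusted p = 0.00272, and adjusted p = 0.177 with an estimated correlation). Pparg, the nuclear receptor that GM-CSF induces in alveolar macrophages, fell from 9.29 ± 0.833 to 0.488 ± 0.145 FPKM and the lysosomal lipase Lipa from 233 ± 7.97 to 81.4 ± 2.93 FPKM. Acsl1 (13 ± 1.59 to 90.7 ± 5.97 FPKM) and the oxidized lipoprotein receptor Olr1 (5.97 ± 0.761 to 49.7 ± 4.03 FPKM) rose. The liver X receptor targets divided, 5 rising and 5 falling of 12 (camera adjusted p = 0.871). The cholesterol exporter Abca1 rose from 10.7 ± 1.97 to 55.6 ± 2.56 FPKM. Abcg1 fell from 104 ± 4.90 to 62.4 ± 2.57 FPKM and Apoe from 48.9 ± 6.09 to 16.9 ± 2.60 FPKM. Srebf1, at 17.8 ± 0.372 FPKM in untreated samples and 17.9 ± 0.423 FPKM with PLG, did not pass. Of 16 fatty acid synthesis and desaturation genes 10 fell and 4 rose (camera adjusted p = 0.169). Fasn (30.9 ± 2.06 to 11.8 ± 0.804 FPKM) and Scd1 (39.9 ± 3.82 to 21.4 ± 1.18 FPKM) fell. Dgat2 (0.256 ± 0.104 to 7.32 ± 0.527 FPKM) and Me1 (2.87 ± 0.693 to 9.60 ± 0.759 FPKM) rose. Of 27 lysosome genes 22 fell and 1 rose (camera adjusted p = 4.52e-08, and adjusted p = 0.128 with an estimated correlation). Falling members included the proton pump subunit Atp6v0d2 (309 ± 14.4 to 86.9 ± 3.84 FPKM), the proteases Lgmn (247 ± 18.4 to 60.5 ± 1.93 FPKM) and Ctsl (109 ± 4.08 to 55.1 ± 1.99 FPKM) and Psap (5931 ± 212 to 2215 ± 63.0 FPKM).

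Stress and metabolic genes moved in both directions. Of 25 NRF2 antioxidant response genes 19 rose and 2 fell, 3 when adjusted over the list alone (camera adjusted p = 4.96e-06, and adjusted p = 0.177 with an estimated correlation). Rising members included the haem-degrading enzyme Hmox1 (114 ± 6.07 to 480.4 ± 37.9 FPKM), Sqstm1 (131 ± 7.85 to 393 ± 33.1 FPKM), Abcc1 (14.7 ± 1.41 to 40.6 ± 2.41 FPKM) and Srxn1 (79.7 ± 3.63 to 177 ± 13.2 FPKM). Of 25 unfolded protein and integrated stress response genes 15 rose and 9 fell (camera adjusted p = 0.0219, and adjusted p = 0.309 with an estimated correlation). Mthfd2 (10.2 ± 1.76 to 33.1 ± 3.54 FPKM), Nupr1 (2.25 ± 0.350 to 8.50 ± 0.762 FPKM) and Sesn2 (13.8 ± 0.585 to 25.5 ± 1.74 FPKM) rose. Of 26 glycolysis and hypoxia-inducible genes 16 rose and 2 fell (camera adjusted p = 0.00432, and adjusted p = 0.265 with an estimated correlation). Pfkfb3, which makes an activator of glycolysis, went from 7.62 ± 0.172 to 41.6 ± 1.91 FPKM, the glucose transporter Slc2a1 from 33.5 ± 1.13 to 65.0 ± 3.11 FPKM and Hif1a from 21.4 ± 2.44 to 42.8 ± 1.26 FPKM. Gapdh, at 259 ± 14.2 FPKM in untreated samples and 284 ± 21.4 FPKM with PLG, did not pass. It passed as higher in 9 of 28 alternatives (adjusted p 0.00314 to 0.386), among them without untreated 2 (0.0390) or PLG 3 (0.00879), and with quantile normalization its log2 fold change was -0.081. Quantile normalization ended the calls of the stress response list and the glycolysis list (camera adjusted p = 0.0640 for each), and a filter of 5 FPKM that of the former (0.0789). Their medians were then 0.42, 0.11 and 0.48, against 0.50 for the stress response list and 0.29 for the glycolysis list. Over 29 camera alternatives the adjusted p ran from 0.00874 to 0.309 for the stress response list and from 8.96e-04 to 0.265 for the glycolysis list. Of 35 nuclear-encoded oxidative phosphorylation genes 14 fell and 1 rose, 0 when adjusted over the list alone (camera adjusted p = 0.0654). The list passed as lower in 9 of 29 camera alternatives (adjusted p 0.00877 to 0.588), among them without PLG 3 (0.0318) or PLG 4 (0.0402). Among those that fell were Sdha (62.2 ± 2.04 to 42.6 ± 2.55 FPKM) and Atp5a1 (162 ± 6.31 to 123 ± 7.26 FPKM). Of 12 mitochondrially encoded genes 8 fell and 0 rose (camera adjusted p = 0.00432, and adjusted p = 0.284 with an estimated correlation). Both mt-Nd1 (1301 ± 54.8 to 805 ± 48.5 FPKM) and mt-Cytb (1280.3 ± 62.3 to 821 ± 63.2 FPKM) fell.

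Proliferation genes fell in larger part with PLG. Of 29 tested G2/M genes 27 fell and 1 rose, with a median of -1.18 (camera adjusted p = 6.40e-10, and adjusted p = 0.0521 with an estimated correlation). Top2a went from 8.19 ± 1.03 to 1.31 ± 0.203 FPKM and the cyclin gene Ccna2 from 3.83 ± 0.437 to 0.353 ± 0.131 FPKM. Of 24 S-phase genes 17 fell and 2 rose (camera adjusted p = 3.14e-04, and adjusted p = 0.128 with an estimated correlation). E2f2 (8.71 ± 0.420 to 1.41 ± 0.107 FPKM) and the ribonucleotide reductase subunit Rrm2 (5.75 ± 1.59 to 0.768 ± 0.230 FPKM) fell. E2f1, at 7.18 ± 1.45 FPKM in untreated samples and 8.24 ± 0.887 FPKM with PLG, did not pass, although it passed as higher in 2 of 28 alternatives (adjusted p 0.0308 to 0.354), among them without untreated 2 (0.0354). Of 19 replication-dependent histone genes 11 fell and 1 rose (camera adjusted p = 0.0130, and adjusted p = 0.415 with an estimated correlation). H1f5 (11.6 ± 2.01 to 1.29 ± 0.548 FPKM) and H4c1 (5.55 ± 1.59 to 1.61 ± 0.593 FPKM) fell. The histone list did not pass with a filter of 5 FPKM, where its median was -0.21, against -0.84 (camera adjusted p = 0.218, and 0.00238 to 0.415 over its 29 camera alternatives). Of 51 ribosomal protein genes 12 rose and 8 fell, 11 and 7 when adjusted over the list alone (camera adjusted p = 0.519). Rplp0, at 368 ± 24.0 FPKM in untreated samples and 378 ± 29.8 FPKM with PLG, did not pass, although with quantile normalization it passed as lower (log2 fold change -0.24; adjusted p 0.00659 to 0.987 over 28 alternatives).

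Markers of cell types were measured in the whole culture, so no cell is named from them. Of 21 macrophage identity genes 15 fell and 3 rose (camera adjusted p = 0.00307, and adjusted p = 0.177 with an estimated correlation). Over the 22 measured members, 1 of them under the filter, the mean log2(FPKM + 1) went from 6.09 ± 0.0634 to 5.64 ± 0.0413. The chemokine receptor Ccr2 fell from 9.88 ± 0.930 to 0.175 ± 0.113 FPKM and Trem2 from 46.6 ± 3.11 to 13.3 ± 0.943 FPKM. Ly6c2, whose reads may be shared with a close paralog, rose from 22.3 ± 2.33 to 118 ± 12.8 FPKM. The GM-CSF receptor chain Csf2rb, at 517 ± 9.26 FPKM in untreated samples and 490.3 ± 24.2 FPKM with PLG, did not pass, although it passed as lower in 2 of 28 alternatives (adjusted p 5.24e-05 to 0.853). Of 17 dendritic cell markers 11 rose and 5 fell (camera adjusted p = 0.0417, and adjusted p = 0.453 with an estimated correlation). Over the 21 measured members the mean log2(FPKM + 1) went from 2.42 ± 0.131 to 3.15 ± 0.0369. The maturation and migration genes Fscn1 (28.5 ± 9.82 to 709 ± 36.6 FPKM), Ccr7 (38.1 ± 10.8 to 542 ± 27.1 FPKM) and Cd83 (12.8 ± 3.37 to 95.0 ± 10.4 FPKM) rose, and Clec9a, a marker of cross-presenting dendritic cells, fell (9.67 ± 1.33 to 2.94 ± 0.163 FPKM). This list's call lay close to the threshold: without untreated 2 its camera adjusted p was 0.0504 and without untreated 4 it was 0.0688. The call was lost in 9 of 29 camera alternatives (adjusted p 0.0159 to 0.453), among them the replicate number as a block (0.0502), a pseudocount of 0.1 (0.0518), a filter of 5 FPKM (0.116), median-of-ratios scaling (0.0660) and removal of GC content (0.0623) or gene length trends (0.0613). The median log2 fold change of the list was 0.74, and 0.66 to 1.07 in the 8 of these alternatives that kept the preset correlation.

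Markers of other cell types moved both ways, and many of them lay under the filter. Of 8 tested neutrophil markers 3 rose, Lcn2 and Camp (0.254 ± 0.351 to 2.40 ± 1.01 FPKM) among them, and 2 fell, among them Mmp8 (camera adjusted p = 0.679). S100a9, at 5.32 ± 3.70 FPKM in untreated samples and 3.80 ± 1.0 FPKM with PLG, did not pass. Over the 16 measured members the mean log2(FPKM + 1) of neutrophil markers went from 1.54 ± 0.135 to 1.93 ± 0.0497. Of 6 granulocyte, mast and basophil markers 3 rose and 2 fell (camera adjusted p = 0.865). Hdc, the histamine-forming enzyme, rose (0.137 ± 0.118 to 17.1 ± 1.51 FPKM). The list's members Siglecf (9.48 ± 0.903 to 1.35 ± 0.217 FPKM) and Ear6 (11.7 ± 3.22 to 1.76 ± 0.442 FPKM) fell, Ear6 being 1 of several near-identical genes. Under 5 members passed the filter in 3 lists, which had no list test. Of 16 lymphocyte markers only Il7r passed the filter, and it fell (124 ± 7.10 to 96.3 ± 6.73 FPKM). Of 3 tested stromal markers 1 rose, Pdgfrb (0.253 ± 0.0786 to 5.18 ± 0.256 FPKM), and 1 fell. Of 3 tested erythroid and megakaryocyte markers 2 rose, Car2 (13.7 ± 1.87 to 76.4 ± 8.37 FPKM) and Pf4 (48.3 ± 6.19 to 98.3 ± 6.89 FPKM), and 1 fell. Over all measured members, the share of summed FPKM went from 3.33% ± 0.534 to 1.98% ± 0.163 for macrophage identity genes, 0.159% ± 0.0174 to 0.619% ± 0.0467 for dendritic cell markers, 0.156% ± 0.0156 to 0.132% ± 0.0130 for neutrophil markers, of which Mmp8 was the most abundant in untreated samples, and 0.0120% ± 0.00172 to 0.0145% ± 0.00175 for granulocyte, mast and basophil markers. It went from 0.0469% ± 0.00727 to 0.0377% ± 0.00583 for lymphocyte, 0.00359% ± 5.35e-04 to 0.00502% ± 6.24e-04 for stromal and 0.0277% ± 0.00286 to 0.0704% ± 0.00734 for erythroid and megakaryocyte markers. The sums include the 3 repeat-like gene models, which made up 0.775% (PLG 3) to 27.8% (untreated 3) of them. All these shares therefore also vary with the level of those models.

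**Figure D2:**
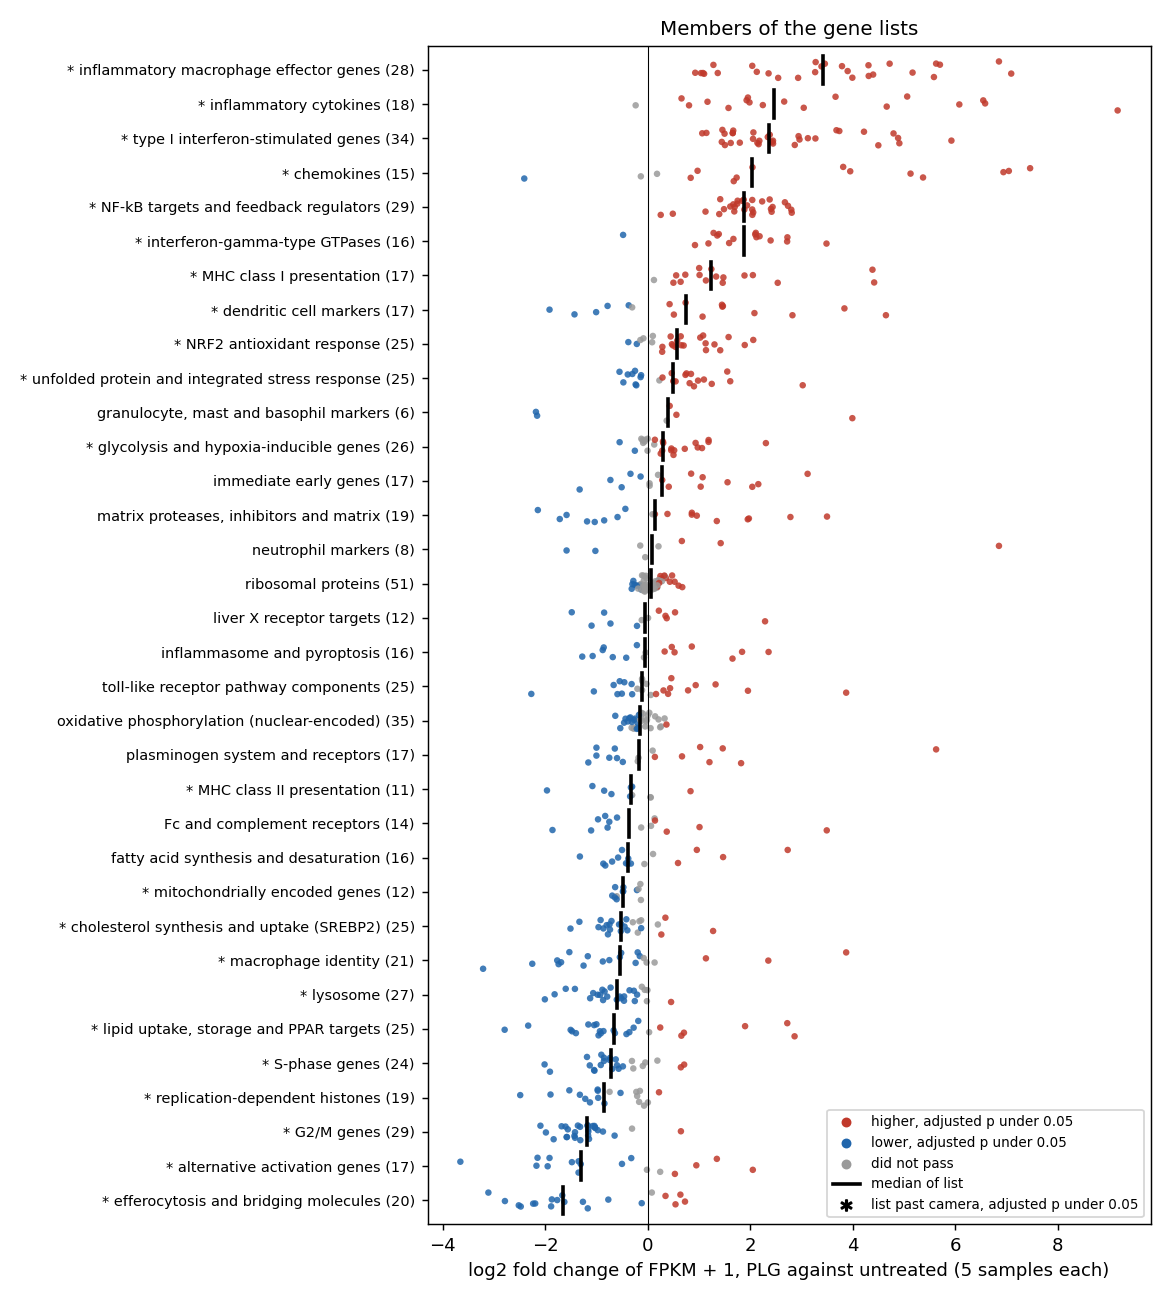
Log2 fold change (FPKM + 1, PLG against untreated, 5 samples each) of the tested members of the 34 gene lists with at least 5 tested genes. Points are genes (red higher, blue lower, grey not passed), the black bar is the list's median and an asterisk marks the 22 lists past the camera threshold, with medians from -1.65 for efferocytosis and bridging molecules to 3.42 for inflammatory macrophage effector genes.

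Across the 37 lists the counts over all genes tested equalled those adjusted over the list alone in 30, and differed by at most 2 genes in the rest. Camera called 11 lists higher and 11 lower at its preset correlation of 0.01, and 4 of these 22 calls, all higher, held with an estimated correlation: inflammatory cytokines, inflammatory macrophage effector genes, type I interferon-stimulated genes and MHC class I presentation. Of the 24 genes fixed as the focus of the comparison, 23 were measured and 16 passed the test, 12 higher and 4 lower. In an exact two-sided permutation test, 17 of the 23 had p = 0.00794, the smallest that 5 against 5 samples can give.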

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

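The counts of other splits were planned, and no test in this part was chosen after its result was seen. Of 100 splits of the 10 samples into 5 and 5, the real one included, 1 gave as many genes as the 6040 of the real split. The highest of the others gave 1. Every other split mixed the groups and so put the treatment difference into the spread within its groups, which leaves few genes to call. The gene counts therefore cannot exclude a chance difference between cultures, since the replicates may be technical. For the gene lists the real split gave 22 and the highest of the others 21, and again 1 of 100 splits gave as many. That margin is thin. The 17 splits that kept 4 samples of a group together gave 16 to 21 lists, and the 82 that mixed 3 and 2 gave 5 to 16 lists. None of these other splits gave more than 1 gene. Splits of both kinds still hold part of the treatment difference, those of the former kind a larger part. Camera at its preset correlation therefore called up to 21 lists in groupings with at most 1 called gene. These counts exclude chance neither for the number of lists nor for each list.

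In 336 groups of 5 values checked (the named genes, the cell type lists, the library totals and 3 gene models), 14, or 4.17%, held a sample far from the other 4. The limit used is passed by about 1 in 20 groups of independent values with a normal spread. Many of the genes were named for a small p or for groups that did not overlap, and some lay near 0. The share therefore cannot be set against that rate. In untreated samples Il6 was at 0.457 FPKM in untreated 2 and at most at 0.013 in the others, Il12b at 2.98 FPKM in untreated 3 against 0.470 to 0.800, and Cxcl1 at 0.281 FPKM in untreated 3 against at most 0.078. Arg1 was at 0.792 FPKM in untreated 1 (others 0.211 to 0.318), E2f2 at 7.97 FPKM in untreated 1 (8.82 to 9.05) and Gbp3 at 14.2 FPKM in untreated 5 (12.3 to 12.8). Untreated 4 stood below the others for Dusp1 at 7.62 FPKM (8.40 to 8.44), H2-DMb1 at 49.7 FPKM (61.7 to 65.2), Sqstm1 at 117 FPKM (131 to 137) and Sesn2 at 12.8 FPKM (13.9 to 14.3). Among PLG samples, Msmo1 was at 15.4 FPKM in PLG 1 (14.3 to 14.6), F10 at 189.7 FPKM in PLG 4 (168 to 174), Srebf1 at 17.2 FPKM in PLG 3 (17.9 to 18.2) and C3 at 198 FPKM in PLG 3 (224 to 233).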

How the results depend on the processing

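The alternatives with voom, the repeat-like models, GC content and gene length were chosen after seeing the data. Leaving out each sample gave 2701 to 2978 genes higher, 2936 to 3133 lower, 10 to 11 lists higher, 11 to 12 lower and 16 to 17 focus genes called. The other 18 settings of filter, scaling, model and covariate gave 2185 to 3360, 2133 to 3641, 9 to 12, 8 to 12 and 15 to 18. Voom on the recovered reads called 3285 higher and 2979 lower. Without untreated 2, PLG 3 and PLG 4 the counts were 2599 and 2964. A fold of at least 2 left 835 higher and 567 lower, by construction. With an estimated correlation camera called 4 lists higher and 0 lower, and fry, which does not compare a list with other genes, called 18 higher and 14 lower of 34. The cause was not tested. All 134 named genes called in the main comparison were called under every setting that tested them except the fold threshold, which 16 missed. Many of them were named for large changes or small p, which made this likely in advance. Over all genes, scaling to a common sum kept 2529 of the 2914 higher and 2165 of the 3126 lower calls. Removal of mitochondrial genes with the same scaling kept 2439 and 2216. Of 22 called lists 17 were called under every setting that tested them at camera's preset correlation. The filter of 5 FPKM left 5 of the named genes and the G2/M list without a test, and removal of mitochondrial genes left out 2 named genes and the mitochondrially encoded list. Scaling moved the share of higher genes among those called from 48.2% to between 41.5% and 54.0%.

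The replicate numbers did not pair the samples: same-numbered samples correlated at -0.121 to 0.0988 in their deviations from the group means, and the own number was best for 1 of 5. With the replicate block 2797 genes were higher, 2988 lower, 10 lists higher and 11 lower, and 16 focus genes passed.

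Among the named genes and the lists, signs changed only for results that had not passed, and over all genes 1 call had the opposite direction, with quantile normalization. The cause was not tested. Quantile normalization gave Myd88 -0.033, H2-Eb1 -0.16, Srebf1 -0.072, Gapdh -0.081, Rplp0 -0.24, Anxa2 -0.11, Axl -0.16 and ribosomal proteins a median of -0.12, with Rplp0 and Axl then past the threshold. Leaving out the repeat-like models and scaling to a common sum gave Myd88 -0.0044, H2-Eb1 -0.016, Srebf1 -0.059, Rplp0 -0.032 and ribosomal proteins -0.0037. Their level as covariate gave H2-Eb1 -0.055, Rplp0 -0.026 and ribosomal proteins -0.047, and leaving out untreated 2, PLG 3 and PLG 4 gave H2-Eb1 -0.083, Rplp0 -0.0013 and ribosomal proteins -0.023. The common sum gave Tlr6 0.021 and Chil3 0.033, and median-of-ratios 0.012 and 0.025. Removal of mitochondrial genes with scaling to a common sum gave 0.0051 and 0.016. Voom gave Chil3 0.028, the GC correction 0.0076, and the length correction Tlr6 0.0041. A filter of 5 FPKM turned the liver X receptor targets to 0.0066 and Fc and complement receptors to 0.064, and no filter the plasminogen system to 0.022. Leaving out a sample gave -0.083 to 0.019 for Tlr6, -0.061 to 0.032 for Chil3, -0.025 to 0.10 for H2-Eb1, -0.0049 to 0.021 for Srebf1 and -0.57 to 0.10 for S100a9. Depth limits Ifnb1 and Il10, which had 13 and 112 reads over the 5 PLG libraries.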

Other observations

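Tests of gene families, of dendritic cell markers, of interferon signals, and of treatment and gene length for the repeat-like models were chosen after the data were seen. Gene families not fixed beforehand, grouped by the letters that start the symbol, were tested for an excess of called genes against all 9803 tested genes with a named symbol (one-sided Fisher's exact test, Benjamini-Hochberg over 346 tests). This test takes the genes of a family as independent, so for genes that vary together its adjusted p-values can be too small. Proteasome genes rose: 9 of 10 Psmb genes, which encode core subunits (adjusted p = 0.00813), and 10 of 14 Psmd genes, a stem named after the regulatory particle, with 1 falling (adjusted p = 0.0404). Psmb9 went from 4.95 ± 0.763 to 15.5 ± 1.85 FPKM and Psmb8 from 16.1 ± 2.08 to 39.3 ± 3.28 FPKM, both subunits of the immunoproteasome, and Psmd10 from 11 ± 0.790 to 30.4 ± 4.23 FPKM and Psmd11 from 13.7 ± 0.474 to 23.6 ± 0.484 FPKM. Of the Psmb genes 3 were also in the fixed lists. The median log2 fold changes of 0.44 for Psmb and 0.31 for Psmd stayed above 0 under every setting. The choice of the families by an excess of rising genes made this likely in advance. Under the scalings 7 to 10 Psmb and 8 to 10 Psmd genes were called higher.

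Sorting nexin genes, which act in endosomal transport, fell in 17 of 28 cases and rose in 3 (Snx, adjusted p = 0.0404), with Snx2 going from 71.4 ± 3.09 to 28.8 ± 0.846 FPKM and Snx5 from 70.2 ± 5.40 to 34.8 ± 2.53 FPKM. Of 55 Atp genes, a stem that joins several kinds of pumps and ATP synthase and has 8 members in the fixed lists, 31 fell and 7 rose (adjusted p = 0.00813), among them proton pump subunits such as Atp6v0a1 (102 ± 6.43 to 38.2 ± 2.17 FPKM) and Atp6v1b2 (177 ± 5.50 to 86.2 ± 2.40 FPKM). Trim genes rose in 20 of 37 cases and fell in 7 (adjusted p = 0.0404), among them Trim30d (9.12 ± 1.46 to 43.1 ± 1.95 FPKM), and 11 of 13 Ifi genes, 5 of them in the fixed lists, rose and 2 fell (adjusted p = 0.00659), among them Ifi44 (0.497 ± 0.141 to 18.2 ± 1.56 FPKM). Of 21 Kif genes, a stem named after motor proteins with 5 members in the fixed lists, 14 fell and 3 rose (adjusted p = 0.0404). Median log2 fold changes were -0.30 for Snx, -0.22 for Atp, 0.24 for Trim, 1.81 for Ifi and -0.55 for Kif. They kept their sign under every setting. The choice of these families by an excess of calls in that direction made this likely in advance. With scaling to a common sum 13 Snx, 22 Atp and 12 Kif genes were called lower. Under the same scaling 18 Trim and 11 Ifi genes were called higher. The stems Il, Gbp, Bcl, Ly (higher) and Cd (lower) passed as well, and also mix genes of unrelated function or overlap the fixed lists. These genes were named after their values were seen, and Trim30 and Ifi genes have close paralogs.

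The repeat-like gene models Gm10800 (chromosome 2, 98666547 to 98667301), Gm10801 and Gm21738 took a variable part of every library, holding 0.116% to 5.23% of assigned reads and 0.775% to 27.8% of summed FPKM, lowest in PLG 3, PLG 4 and untreated 2. Gm10800 ran from 1339.3 to 43769.5 FPKM among PLG samples and from 8220.98 to 59684.9 FPKM among untreated samples. Samples of a group share the treatment, so treatment does not account for this spread within the groups. An effect of treatment on the mean level between the groups stays open (exact two-sided permutation p = 0.238). Genomic DNA in the libraries stays open: olfactory receptor reads against the level gave Spearman's rho = 0.139 (permutation p = 0.704) and Pearson's r = -0.178 (permutation p = 0.512, 100000 resamples) over deviations of 10 samples from group means, and r = -0.487 without the 2 samples farthest out, with opposite signs in the 2 groups, whose 5 samples each are too few for a test. GC content and gene length could matter in PLG samples, where the difference between low and high samples gave, across genes, rho = -0.142 with GC content (-0.0067 in untreated samples) and -0.222 with gene length (-0.0566), genes not being independent replicates. For the spread within the groups, genomic DNA, GC content and gene length cannot be told apart.

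Of 17 dendritic cell markers 11 rose and 5 fell, and of 21 macrophage identity genes 15 fell and 3 rose, with list calls that were lost at adjusted p = 0.453 and 0.177 with an estimated correlation. The call of the former was lost in 9 of 29 camera alternatives. A higher share of dendritic cells would raise their markers together. Of 14 markers held by no other list 11 rose and 3 fell (Clec9a, and Kmo and Kit, named after their values were seen). Over all 9997 tested genes 2914 rose and 3126 fell. The markers cannot decide, since the limit of 3 falling markers was set after the data were seen and Clec9a marks only some dendritic cells. A higher share of dendritic cells and a change of state within the cells both stay open and were not tested apart.

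All tested type I interferon-stimulated genes and NF-kB targets rose (the list call of the latter had adjusted p = 0.0577 with an estimated correlation), and a signal through Tlr4 beside Tlr2 is a candidate explanation. The 10 samples include none that lacks a receptor, and Ifnb1, with 13 reads over the PLG libraries and 0 over the untreated, was too low at 24 h to help. The explanations cannot be told apart here, because every PLG sample carries the same treatment.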
